A study of Drosophila melanogaster with 27 samples.

How the data were processed

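RNA sequencing of whole flies gave 27 libraries, 3 for each combination of injection (Tris, c-di-GMP, cGAMP) and time (6, 12 and 24 h). Per the labels, adult flies were kept at 25 °C with 12 h of light and 12 h of dark, total RNA was extracted with Trizol, and directional libraries were made with a NEBNext Ultra kit. The deposited raw table holds counts of reads per gene. Per the submitters' processing notes, Trimmomatic, STAR 2.5.3, featureCounts and DESeq2 were used with the genome BDGP6; settings and order were not given. The deposited normalized table, made by the authors, holds signal equal to the raw counts divided by 1 size factor per library (0.494 to 1.95), with departures of at most 6.66e-16 of the value; it was not used for tests. Of the nonzero raw counts 58.0 to 74.5% per library were even numbers, which leaves open that both mates of a read pair were counted. The sex of the flies and a sequencing batch were not used here, since the labels name neither.

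The table covers 15009 genes, 14620 to 15005 of which had counts in a library. Symbols were found for 14915 gene identifiers in the reference table, and coordinates are those of the annotation of the same assembly, BDGP6, for the whole gene. Libraries held 50771139 to 114717164 counts in total and 20458214 to 43962847 outside ribosomal RNA and 7SL RNA.

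Raw counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were to be kept by filterByExpr, which removed 0 genes, TMM factors were used, and 1 coefficient per group was fitted to all 27 libraries by the robust quasi-likelihood method (glmQLFit, glmQLFTest). Each of the 9 contrasts between injections at a matched time was tested with Benjamini-Hochberg adjustment at 0.05. A 2-degree F test asked whether the change with cGAMP differs between times, and another asked what changes with time in Tris. Standard errors and 95% intervals come from the fitted log2 changes and the moderated spread, with 3 libraries per group. The p-values measure only the spread between libraries, since the labels do not say that libraries of a group come from separate cultures or cohorts of flies.

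The design, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. That set was RLE factors, DESeq2 1.42.0 (Wald and likelihood ratio tests), no filter on low counts, the replicate number as a block, only the libraries of the groups compared, and each library left out in turn. Chosen after seeing the data were a library batch term with 4 levels (the replicate number, with libraries under 50% ribosomal and 7SL RNA as a level of their own), replicates 1 and 2 only with the block, removal of ribosomal and 7SL RNA before normalization, a minimum mean count of 100 (11792 genes), and the naming rule applied to the paired fits.

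The labels number the libraries of a group B1 to B3 without stating what the numbers stand for, so pairing was checked across the genes: in 7 of the 9 comparisons every pair of libraries of the same number correlated above 0.1 after removal of group means. In 5 of these 7 each library of the group named first was also closest to the one of its own number in the other group. This held for 2 of 3 numbers in c-di-GMP against Tris and 1 of 3 in cGAMP against c-di-GMP at 12 h. The closest library was not sought in the reverse direction. The correlations for numbers 1, 2 and 3 were 0.53, 0.35 and 0.52 for cGAMP against Tris at 6 h, 0.73, 0.80 and 0.95 at 12 h and 0.84, 0.78 and 0.92 at 24 h. For c-di-GMP against Tris and cGAMP against c-di-GMP at 6 h replicate 2 did not pair (−0.02 and −0.31). At 12 and 24 h replicate 3 was of low ribosomal RNA share in every group, which by itself makes libraries of all 3 numbers correlate. Passing 0.1 there does not show that numbers 1 and 2 pair, and only the check of the closest library bears on that. Where all 3 numbers passed 0.1, blocked values stand beside the results whose call or count they change. No pair of replicates within a group was a copy, as the lowest chi-square per gene of these pairs was 150. Libraries of different groups were not compared in this way.

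Named genes were, for each comparison, up to 12 risen and 8 fallen genes with the largest change past adjusted p 0.05 whose groups lie fully apart and whose mean log2 CPM is at least 0; all members of the 4 immune lists (STING, IMD-type antimicrobial peptides, IMD pathway, RNA interference); up to 4 members with the lowest p of any other list; and up to 15 genes per F test. In the paired fits the rule required adjusted p under 0.05 in both the blocked and the library batch fit and the same direction in all 3 pairs. The 23 lists hold 485 genes, 463 of them measured; they cover, besides those 4, Toll effectors, the Toll pathway, JAK-STAT, autophagy, heat shock proteins, JNK and wounding, haemocytes and melanisation, the proteasome, ribosomal proteins, glutathione transferases and cytochromes P450, insulin and lipid use, purine metabolism, digestive enzymes, the clock, ovary and egg shell, testis and accessory gland, muscle, neurons and eye, and fat body. Of the ovary list 9 of 23 genes are in the table. Lists were tested with camera (preset correlation 0.01, and estimated) and fry, adjusted over the lists of a comparison.

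The fits were tested on simulated data of the same size (15009 genes, 100 genes changed 2-fold and 100 changed 4-fold). For cGAMP against Tris at 6 h the unblocked fit recovered 12% and 46% of them, the blocked fit 54% and 89% and the library batch fit 79% and 95%; at 12 h the shares were 17% and 59%, 54% and 94%, and 87% and 100%; at 24 h they were 13% and 51%, 54% and 95%, and 78% and 97%. The unblocked fit made 0 false calls at each time, the blocked fit 4, 2 and 2, and the library batch fit 4, 18 and 10. The simulated counts were drawn from the means, batch effects and dispersions of the library batch fit. That fit is thus favoured by construction, and the shares do not rank the fits on the real data. Shared Tris libraries were simulated 10 times from the library batch fit with both compounds set to no effect. For the other splits of the samples, each contrast was refitted over the 10 splits of its 6 libraries, and the F tests over 80 arrangements drawn at random. With the block, times were drawn within each replicate number, in all 36 arrangements of Tris and in 50 for the cGAMP response, a number set by running time. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.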

Results

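Whole adult flies (Drosophila melanogaster, 3 to 5 days old) received 69 nl of Tris buffer, c-di-GMP or 2'3'-cGAMP by injection into the thorax, and RNA was sequenced 6, 12 or 24 h later. Both compounds are cyclic dinucleotides, a class of small signalling molecules that the innate immune receptor Sting binds. c-di-GMP is made by bacteria and 2'3'-cGAMP (cGAMP) by enzymes of the cGAS family in animals. Each of the 9 groups held 3 libraries, numbered 1 to 3, which gives 27 in all. The libraries held 50771139 to 114717164 counts (median 83639197). Of these, 20458214 to 43962847 (median 30249655) lay outside ribosomal RNA and 7SL RNA. Whether both mates of a read pair were counted is unknown. The labels give the injected volume but not the concentrations, so whether the doses of the compounds were matched is unknown.

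The first comparison asked which genes responded to cGAMP after 6 h, against Tris-injected flies of the same time. PGRP-SC2 (FBgn0043575; BDGP6 2R 8716950–8717695), a secreted enzyme that cleaves bacterial peptidoglycan, rose by 2.54 ± 0.32 (log2 fold change ± SE, n = 3 per group) in the edgeR quasi-likelihood test without a block (Benjamini-Hochberg adjusted p = 0.000571). Its level went from 21.9 ± 4.05 to 127 ± 17.5 CPM (counts scaled to library size, mean ± SD). CG34291 (FBgn0085320; 3R 26425290–26425781), a gene without an assigned function in the annotation used here, rose by 3.06 ± 0.36 in the same test, from 4.4 ± 0.678 to 36.7 ± 17.7 CPM (edgeR adjusted p = 0.000478). PGRP-LC (FBgn0035976), the membrane receptor that starts signalling in the IMD pathway, rose by 1.07 ± 0.20 (edgeR adjusted p = 0.0438). CecA1 (FBgn0000276; 3R 30210874–30211273), which encodes a cecropin, a peptide that kills bacteria, rose by 2.62 ± 0.47 (edgeR adjusted p = 0.0372). Ets21C (FBgn0005660; 2L 544925–552923), a transcription factor of stress responses, rose by 1.88 ± 0.37 and tok (FBgn0004885), a metalloprotease of the tolloid family, by 1.42 ± 0.18 (edgeR adjusted p = 0.0443 and 0.000571).

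Other named genes of the unblocked edgeR test at 6 h were the serpin Spn88Eb, the dipeptidyl peptidase gene ome, the glutamate receptor-associated gene Nmda1, the chloride channel gene ClC-b, CG6912, CG7016 and CG6429, which rose by 1.19 to 2.56. CG4950 and CG2187 fell by 1.97 and by 1.52 (log2). In all, 18 of 15009 genes changed, 16 of them higher and 2 lower, and 597 genes had an unadjusted p under 0.05. With the replicate number as a block, which pairs libraries of the same number, 480 genes changed (236 higher, 244 lower), among them all 18. The blocked count was 213, 210 and 549 without cGAMP replicates 1, 2 and 3. It was 288, 408 and 471 without Tris replicates 1, 2 and 3. DESeq2 gave 112 genes, and no gene passed with only the libraries of the groups compared in the edgeR fit. Without a block the edgeR count was 3, 4 and 62 without Tris replicates 1, 2 and 3, and 4 and 3 without cGAMP replicates 1 and 2. A fit with a library batch term, chosen after seeing the data, gave 744 genes (484 higher, 260 lower), 405 of them shared with the blocked fit. In it Tris and c-di-GMP replicate 3 form a batch level of their own, which takes up much of what sets Tris replicate 3 apart. Without Tris replicate 3 this fit gave 786 genes, 687 of them shared with the 744. Replicates 1 and 2 alone, likewise chosen after seeing the data, gave 832. The 3 libraries of 1 group lay fully apart from those of the other in 9.68% of genes, where chance gives 10% if all 6 libraries are exchangeable. With the groups swapped within replicate pairs the share was 5.26% on average (highest 7.77%).

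Sting itself (FBgn0033453; 2R 9842686–9845512) rose with cGAMP at 6 h by 3.24 ± 0.43 in the blocked edgeR fit (adjusted p = 0.000175), from 15.6 ± 17.8 to 97.8 ± 28.1 CPM. Without the block its change was 2.65 ± 0.92 and did not pass (edgeR adjusted p = 0.662). Srg1 (FBgn0039239), named as a STING-regulated gene, rose by 2.97 ± 0.82 in the blocked fit (edgeR adjusted p = 0.0494). The NF-kappaB factor Rel (FBgn0014018) rose by 1.35 ± 0.23, the IKK-gamma subunit key (FBgn0041205) by 1.92 ± 0.34 and the IMD inhibitor pirk (FBgn0034647) by 1.09 ± 0.27 in that fit (edgeR adjusted p = 0.00162, 0.00218 and 0.0282). AGO2 (FBgn0087035), the Argonaute that carries antiviral small interfering RNAs, rose by 1.55 ± 0.20 and Dcr-1 (FBgn0039016), the Dicer of the microRNA pathway, by 0.64 ± 0.13 in the blocked fit (edgeR adjusted p = 0.000129 and 0.00568). CecC and CecB rose by 3.59 ± 0.83 and 4.54 ± 0.93 in it (edgeR adjusted p = 0.0178 and 0.00711). The cecropin genes are close copies, and the labels do not say how reads that match several of them were counted. Gcat (FBgn0036208), an enzyme of threonine breakdown, fell by 2.48 and Sodh1, a sorbitol dehydrogenase, by 2.05 on the log2 scale in the blocked fit (edgeR adjusted p = 0.000113 and 0.00161).

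Of the gene lists fixed beforehand, the STING, antimicrobial peptide and IMD lists passed camera with an estimated correlation at 6 h in the unblocked fit, and none of these 3 passed it in the blocked fit. The Toll effector and Toll pathway lists passed in neither (adjusted p = 0.89 and 0.97 without a block, 0.73 and 0.87 with it). The 8 STING genes had a median change of 1.61 in the unblocked fit, with 0 members past the threshold over all genes and 5 when adjusted over the list alone (Sting, Srg1, Srg3, Nazo and Vago). The 13 antimicrobial peptide genes of the IMD type had a median change of 1.62, with 1 member changed over all genes and, adjusted over the list alone, 7 higher and 1 lower (edin). The 20 IMD pathway genes had a median change of 0.35, with 2 members higher and 4 when adjusted over the list alone. The 12 RNA interference genes had a median of 0.32, with 0 members changed and 2 higher when adjusted over the list alone. In the blocked fit 2 STING, 6 antimicrobial peptide, 5 IMD and 2 RNA interference genes passed over all genes. By camera with a preset correlation the adjusted p was 1.9e-12 for the STING list, 5.6e-17 for the peptides, 3.8e-09 for the IMD list and 0.00033 for RNA interference. With an estimated correlation it was 0.0040, 0.012, 0.0019 and 0.11, so that the first 3 held in the unblocked fit. In the blocked fit none of the 4 held with an estimated correlation (adjusted p = 0.077 for the STING, IMD and RNA interference lists and 0.16 for the peptides).

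**Figure D1:**
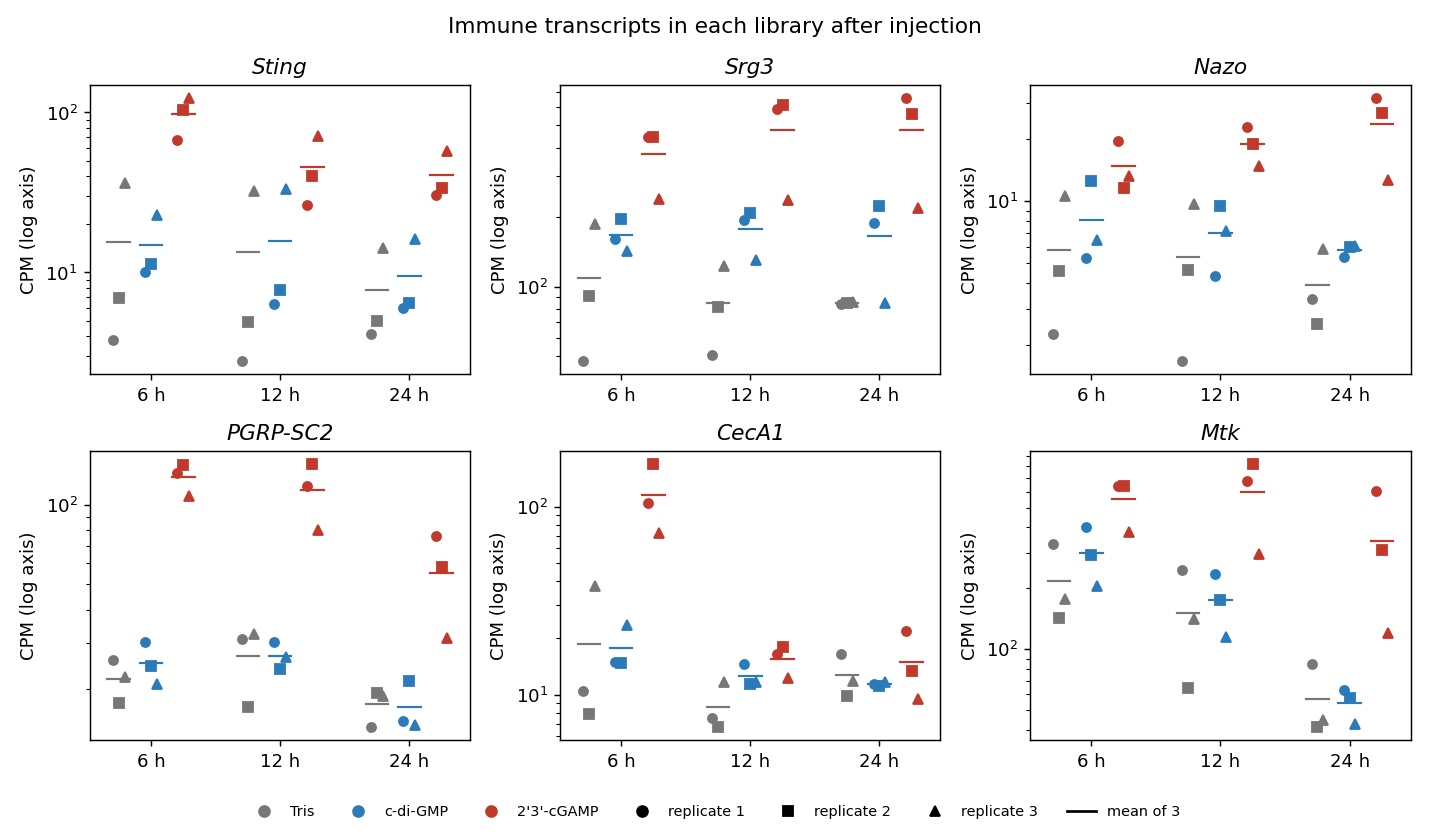
CPM (log scale) of 6 immune genes in each of the 27 libraries, by treatment and time, with group means. For PGRP-SC2 at 6 h the cGAMP mean was 127 CPM and the Tris mean 21.9; for Sting the Tris mean of 15.6 includes replicate 3 at 36.1.

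At 12 h after injection, PGRP-SC2 was the 1 gene that passed against Tris in the unblocked edgeR fit. It rose by 2.08 ± 0.31 (log2 ± SE, n = 3 per group), from 26.8 ± 8.39 to 114 ± 31.5 CPM (edgeR adjusted p = 0.0257), and by 2.06 ± 0.28 in the blocked fit (edgeR adjusted p = 0.00204). In the blocked edgeR fit Sting rose by 2.30 ± 0.42 (adjusted p = 0.0304). The antifungal peptide gene Mtk (FBgn0014865; 2R 15408846–15409113) rose from 151 ± 91.6 to 598 ± 271 CPM (edgeR adjusted p = 0.0333). PGRP-SA (FBgn0030310), a circulating sensor of peptidoglycan upstream of Toll, rose by 1.69 ± 0.32 (edgeR adjusted p = 0.032). Gcat fell by 2.18 and Tdh, the threonine dehydrogenase that acts before it, by 1.15 in the blocked fit. The other named genes of that fit were lncRNA:CR32368, CG17264, LysX, Spn88Eb, CG7016, CG34291, CG16762 and the neprilysin-like gene Nepl13 upward and CG11842 downward.

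With the block 24 genes changed at 12 h (20 higher, 4 lower). That count was 4, 4 and 88 without Tris replicates 1, 2 and 3 and 5, 2 and 40 without cGAMP replicates 1, 2 and 3, so that most of these calls were lost without 1 library of replicates 1 or 2. The unblocked edgeR fit gave 1 gene with 332 at an unadjusted p under 0.05, DESeq2 30, the library batch fit 179 and replicates 1 and 2 alone 297. With only the libraries of the groups compared in the fit no gene passed, so the call of PGRP-SC2 was lost. The unblocked count was 7 without Tris replicate 3 and 0 without Tris replicate 1 or 2 or cGAMP replicate 1 or 2. Groups lay fully apart in 3.6% of genes (10% by chance for exchangeable libraries, 1.46% on average and 1.57% at most with swaps within replicate pairs). The STING list had a median change of 2.16, the peptides 1.68, the IMD list 0.33 and RNA interference 0.16, with 5, 4, 3 and 0 members higher when adjusted over the list alone. Camera with an estimated correlation gave adjusted p = 0.00042, 0.0020, 0.00042 and 0.57 for these lists in the unblocked fit, and 0.021, 0.033, 0.021 and 0.48 in the blocked fit.

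At 24 h 3 of the 8 STING genes passed with cGAMP in the blocked edgeR fit. Nazo (FBgn0037562), an antiviral gene downstream of Sting, rose by 2.69 ± 0.55 in the blocked edgeR fit (log2 ± SE, n = 3 per group; adjusted p = 0.0417). Sting rose by 2.61 ± 0.42 and Srg3 (FBgn0053926) by 2.44 ± 0.49 in it (edgeR adjusted p = 0.00753 and 0.0366). Mtk rose by 2.47 ± 0.38, from 56.8 ± 23.8 to 344 ± 243 CPM, key by 1.95 ± 0.34 and PGRP-SC2 by 1.60 ± 0.28 (edgeR adjusted p = 0.00623, 0.0145 and 0.0145). Dcr-1 rose by 0.61 ± 0.13 (edgeR adjusted p = 0.0448). ninaD (FBgn0002939), a scavenger receptor for carotenoids, fell by 3.49 in the blocked fit. The gut serine protease gene Jon65Aii fell by 2.93, the lysosomal mannosidase gene LManIII by 2.48 and the gut lipase gene mag by 1.90 in it.

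In the unblocked edgeR fit 0 genes passed at 24 h, with 624 at an unadjusted p under 0.05. The blocked fit called 39 (30 higher, 9 lower), DESeq2 42, the library batch fit 262 and replicates 1 and 2 alone 538; the unblocked count was 11 without cGAMP replicate 3 and 2 without Tris replicate 3. The blocked count was 7, 0 and 13 without Tris replicates 1, 2 and 3 and 0, 8 and 137 without cGAMP replicates 1, 2 and 3, so that no blocked call at 24 h stayed without Tris replicate 2 or cGAMP replicate 1. Groups lay fully apart in 6.37% of genes, against 10% by chance for exchangeable libraries and 1.84% on average (highest 3.52%) with swaps within replicate pairs. The STING list had a median change of 2.47, the peptides 0.32, the IMD list 0.43 and RNA interference 0.22; adjusted over the list alone, 6, 1, 3 and 1 members were higher, and edin and 1 IMD gene (PGRP-SC1a) lower. Camera with an estimated correlation gave adjusted p = 0.0017, 0.79, 0.0032 and 0.18 for these lists in the unblocked fit, and 0.045, 0.79, 0.075 and 0.092 in the blocked fit.

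The median change of the STING list differed between the replicate pairs. At 6 h it was 3.39 and 2.68 for pairs 1 and 2 and 0.33 for pair 3; at 12 h it was 3.20, 2.82 and 0.82, and at 24 h 2.87, 2.57 and 1.58. The antimicrobial peptide list changed by 1.74, 3.67 and 0.92 in the 3 pairs at 6 h. In Tris the STING list of replicate 3 lay 1.90, 1.10 and 0.24 above the mean of replicates 1 and 2 at 6, 12 and 24 h, as the median over its 8 genes. In cGAMP replicate 3 the difference was −0.54, −0.91 and −1.32.

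**Figure D2:**
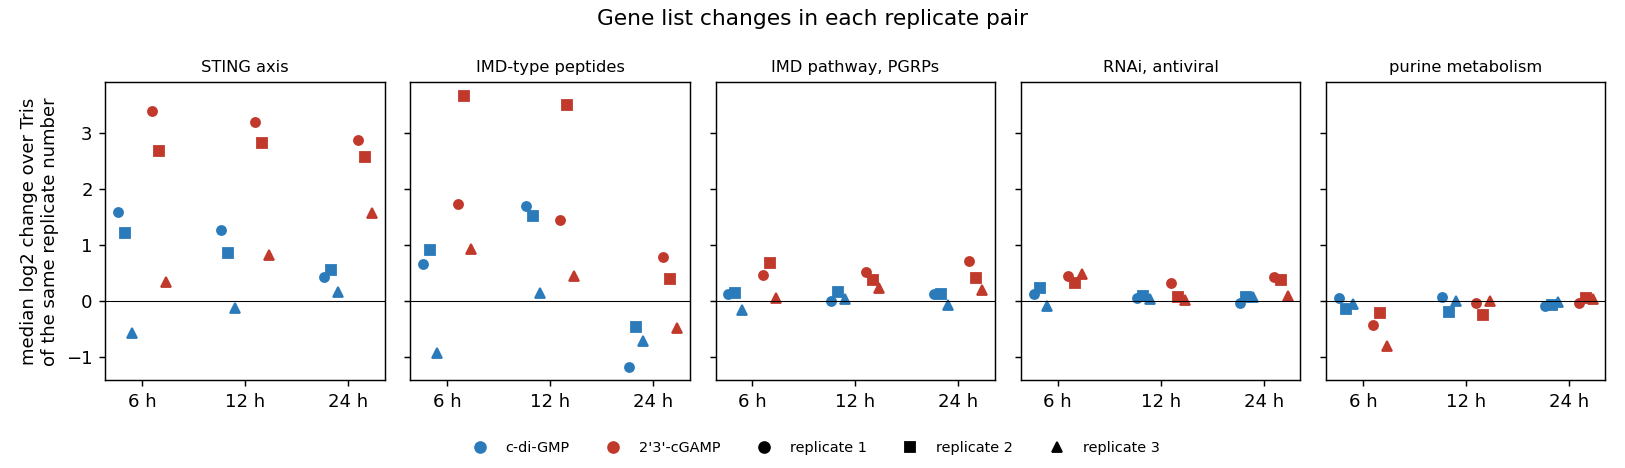
Median log2 change against Tris of 5 gene lists in each replicate pair, for both compounds and 3 times (colour shows the compound, marker shape the pair). For cGAMP at 6 h the STING list changed by 3.39 and 2.68 in pairs 1 and 2 and by 0.33 in pair 3.

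The comparison of c-di-GMP with Tris asked whether a bacterial cyclic dinucleotide changes the same genes. The 95% interval of the Sting change in the unblocked edgeR fit was −1.88 to 1.73 at 6 h, −1.57 to 2.05 at 12 h and −1.52 to 2.10 at 24 h. With the block it was −0.37 to 1.29 at 12 h and −0.46 to 1.21 at 24 h. For PGRP-SC2 the interval was −0.43 to 0.83 at 6 h, −0.63 to 0.63 at 12 h and −0.67 to 0.59 at 24 h in the unblocked fit. The interval of the cGAMP change lay above these, from 1.87 at 6 h and 1.43 at 12 h. For Srg3 it was −0.43 to 1.66, 0.01 to 2.11 and −0.09 to 2.01 in the unblocked fit, and with the block 0.01 to 1.98 at 12 h and −0.08 to 1.88 at 24 h. The secreted antiviral factor Vago (FBgn0030262) had an interval of −0.83 to 2.38 at 6 h.

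No gene passed for c-di-GMP in the edgeR fit without a block: 0 at each time, with 69, 99 and 65 genes at an unadjusted p under 0.05 at 6, 12 and 24 h. The counts were also 0 with DESeq2 (108, 127 and 80 genes at an unadjusted p under 0.05), with the block at 12 and 24 h (267 and 161) and with the library batch (479, 587 and 348). Groups lay fully apart in 4.34%, 1.96% and 1.97% of genes, against 10% by chance for exchangeable libraries. Swaps within replicate pairs gave 1.62% and 1.64% on average at 12 and 24 h (highest 1.82% and 1.75%). At 6 h, where replicate 2 did not pair, swaps gave 4.36% on average and 4.68% at most, so the real share did not exceed them. In replicates 1 and 2 alone 8 genes rose at 6 h, in a fit with the block although replicate 2 did not pair in this comparison. The lectin gene lectin-37Da rose by 2.62 ± 0.28 and Vago by 1.74 ± 0.22 (log2 ± SE, n = 2 per group; edgeR adjusted p = 0.00334 and 0.00812). The others were CG18493, CG31041, CG42807, CG17224, CG3987 and Charon, which rose by 1.09 to 1.46. In the unblocked fit of all libraries lectin-37Da changed by 0.32, Vago by 0.77 and Charon by −0.13, and none of the 8 passed. The fit of replicates 1 and 2 called 0 genes at 12 h and 24 h.

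The STING list moved by a median of 0.36, 0.44 and 0.38 with c-di-GMP at the 3 times, with 0 of 8 members changed over all genes and 0 when adjusted over the list alone. Camera gave adjusted p = 0.0013, 0.00021 and 0.0057 with the preset correlation and 0.95, 0.22 and 0.34 with an estimated one. The antimicrobial peptide list moved by −0.07, 0.54 and −0.91, with 1 member (edin, at 12 h) higher when adjusted over the list alone. Its preset calls at 12 and 24 h did not hold with an estimated correlation (adjusted p = 0.089 and 0.093). Adjusted over the list alone, 0 members of the IMD and RNA interference lists changed at the 3 times. With 3 libraries per group, intervals this wide do not show that c-di-GMP leaves these genes unchanged.

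Compared directly at matched times, cGAMP exceeded c-di-GMP for several immune genes. At 6 h CecA1 was higher by 2.70 ± 0.48 and CG34291 by 2.59 ± 0.35 in the unblocked edgeR fit (log2 ± SE, n = 3 per group; adjusted p = 0.031 and 0.00273). PGRP-SC2 was higher by 2.34 ± 0.32 (95% lower bound 1.67) and tok by 1.23 ± 0.18 (edgeR adjusted p = 0.00273 and 0.00372). CG6429 was higher by 1.61, the zinc transporter gene Zip89B by 1.31, Ccdc85 and CG6330 were also higher, and CG2187 was lower, at −1.42. PGRP-SC2 was higher by 2.08 ± 0.31 at 12 h (interval 1.43 to 2.74; edgeR adjusted p = 0.0256). At 24 h Mtk was higher by 2.47 ± 0.38 (interval 1.68 to 3.27) and Sting by 2.24 ± 0.41 (1.37 to 3.10) in the blocked edgeR fit (adjusted p = 0.0199 and 0.042). PGRP-SC2 was higher by 1.65 ± 0.28 in it (edgeR adjusted p = 0.0247), and ninaD, Jon65Aii, CG17192 and LManIII were lower. The interval for Sting was 0.80 to 4.65 at 6 h and −0.31 to 3.38 at 12 h without a block, and 0.98 to 2.68 at 12 h with it, and Sting did not pass in these tests (edgeR adjusted p = 0.702, 1 and 0.142).

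In the unblocked fit 9 genes differed between the compounds at 6 h (8 higher with cGAMP, 1 lower), 1 at 12 h and 0 at 24 h by edgeR, with 464, 202 and 330 genes at an unadjusted p under 0.05. DESeq2 gave 93, 7 and 19. No gene passed at 6 or 12 h with only the libraries of the groups compared in the edgeR fit. The blocked fit gave 6 at 12 h and 17 at 24 h, the library batch fit 630, 48 and 106, and replicates 1 and 2 alone 570, 116 and 180. At 6 h the unblocked count was 2, 3 and 4 without c-di-GMP replicates 1, 2 and 3 and 3 without either cGAMP replicate 1 or 2. At 12 h it was 0 without any 1 of the c-di-GMP replicates or cGAMP replicate 1 or 2. At 24 h it was 1 without cGAMP replicate 3. The blocked count at 12 h was 0 without c-di-GMP replicate 1 or 2 or cGAMP replicate 2, 1 without cGAMP replicate 1 and 2 without c-di-GMP replicate 3. At 24 h it was 0 without replicate 1 or 2 of either compound, so that the calls of Mtk and Sting were lost, 2 without c-di-GMP replicate 3 and 41 without cGAMP replicate 3. Groups lay fully apart in 8.16%, 2.64% and 4.70% of genes, against 10% by chance for exchangeable libraries. Swaps within replicate pairs gave 2.18% and 1.63% on average at 12 and 24 h (highest 2.83% and 2.86%). At 6 h, where replicate 2 did not pair, swaps gave 7.89% on average and 10.9% at most, so the real share did not exceed all swaps. The STING list differed by a median of 1.22, 1.44 and 2.01 (camera with an estimated correlation in the unblocked fit, adjusted p = 0.039, 0.0015 and 0.0027). The peptides differed by 1.65, 0.99 and 1.29 (adjusted p = 0.028, 0.047 and 0.16) and the IMD list by 0.30, 0.20 and 0.33 (adjusted p = 0.0018, 0.00025 and 0.0059). The RNA interference list differed by 0.34, −0.01 and 0.13 (adjusted p = 0.14, 0.78 and 0.23). In the blocked fit the STING and IMD lists held at 12 h (adjusted p = 0.034 and 0.028) but not at 24 h (0.065 and 0.11), and the peptides did not hold at 12 h (0.25).

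Both sets of changes were measured against the same 3 Tris libraries at each time, which cannot be divided so that each compound keeps at least 2. Across 11988 genes, which are not independent replicates, the changes with cGAMP and c-di-GMP correlated at 0.28, 0.49 and 0.62 at 6, 12 and 24 h without a block (covariance 0.034, 0.049 and 0.072). In 10 simulated sets of libraries in which neither compound had an effect, the mean correlations were 0.22, 0.50 and 0.50 (covariance 0.0285, 0.0312 and 0.0314). Separate controls would give a covariance of 0. The simulation kept the batch effects, so at 6 h the correlation also reflects the composition of cGAMP replicate 3. With cGAMP set to its fitted effect, which includes estimation noise, and c-di-GMP without one, the correlations were 0.19, 0.30 and 0.26 (covariance 0.0291, 0.0302 and 0.0316). In the library batch fit the observed correlations were 0.45, 0.48 and 0.61. With neither compound having an effect, the simulated ones in that fit were 0.47, 0.50 and 0.49. The unblocked, blocked and library batch fits called 0 genes for c-di-GMP, so an overlap of calls was not possible in them. In replicates 1 and 2 alone all 8 genes called for c-di-GMP at 6 h were also called for cGAMP, against 0.353 in independent lists, and part of that excess may come from the shared Tris libraries.

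The change of the cGAMP response with time was tested by an F test of the difference between the times. CecA1, which rose at 6 h, had changes at 12 and 24 h that differed from its change at 6 h by −2.67 and −3.27 (log2) in the library batch fit (edgeR adjusted p = 0.0221). It was not called in the blocked or unblocked fit. In the blocked fit 8 genes differed between the times, among them mdy (FBgn0004797), a diacylglycerol acyltransferase that makes stored fat, which changed by −1.13 at 6 h and 0.03 at 24 h (edgeR adjusted p = 0.0497). The unblocked edgeR fit called 0 genes with 98 at an unadjusted p under 0.05, DESeq2 2, the library batch fit 23 and replicates 1 and 2 alone 27.

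In Tris-injected flies alone, the antibacterial peptide gene DptA (FBgn0004240) decreased by 3.11 from 6 to 24 h in the blocked edgeR fit (log2; adjusted p = 0.0483) and was not called in the library batch fit. At 6 h the peptide list was higher in Tris replicate 3 than in replicates 1 and 2 (median 6.36 against 3.39 and 3.36 log2 CPM), while DptA was at 340, 166 and 209 CPM in replicates 1, 2 and 3. The Toll-induced peptide gene BomS2, the clotting factor gene fon and the heat shock gene Hsp70Aa also fell, fon by 0.98 and Hsp70Aa by 1.18, over the same span and with the same adjusted p. The Hsp70 genes are near-identical copies, so the value for one of them is uncertain. The clock gene vri was higher by 0.60 at 12 h and lower, at −0.62, at 24 h than at 6 h. The thioester protein gene Tep2 fell by 1.25 in the library batch fit (edgeR adjusted p = 0.00372). The blocked fit called 9 genes, the unblocked edgeR fit 0 with 250 at an unadjusted p under 0.05, DESeq2 10, the library batch fit 43 and replicates 1 and 2 alone 27.

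Among the other 19 lists, 4 of 13 purine metabolism genes, all of purine synthesis, fell with cGAMP at 6 h in the blocked fit, and the list median was −0.60. Prat2 fell by 1.23, Paics by 1.21, Pfas by 0.90 and Adsl by 0.61 (log2; edgeR adjusted p = 0.00162, 0.00284, 0.0208 and 0.0205). This list also differed with library composition, by −1.36 in cGAMP replicate 3 and −0.44 in Tris replicate 3 against replicates 1 and 2 at 6 h, which the block does not remove. In the library batch fit Prat2 fell by 0.97, Paics by 0.93, Pfas by 0.62 and Adsl by 0.60 (edgeR adjusted p = 0.000327, 0.000569, 0.00955 and 0.0117), and replicates 1 and 2 alone called Prat2 and Paics. The list had adjusted p = 0.79, 0.077 and 0.037 in the unblocked, blocked and library batch fits by camera with an estimated correlation. The insulin and lipid list (20 genes) had Pepck1, of glucose synthesis, fall by 1.48 and the fatty acid synthase gene FASN1 by 1.01 in that fit. The list of glutathione transferases and cytochromes P450 (24 genes) had Cyp6g1 fall by 1.63 and Cyp28d1 by 0.87. The chaperone genes Hsc70-3 and DnaJ-1 (list of 17) rose by 0.79 and 0.72. In the list of haemocytes and melanisation (15 genes) the scavenger receptor gene crq rose by 0.83, and He and fon fell by 2.23 and 0.76. The haemocyte and chaperone lists also differed with library composition at 6 h, which the block does not remove. Against replicates 1 and 2 they lay at −0.92 and −0.86 in cGAMP replicate 3 and at −0.12 and −0.18 in Tris replicate 3. The testis list lay at 1.13 in cGAMP replicate 3 and at −0.101 in Tris replicate 3. The Toll effector list was lower in cGAMP replicate 3 than in Tris replicate 3. The changes of djl and BaraA1 given below therefore carry the same limit. For the other lists too, the block does not remove such differences at 6 h. In the JAK-STAT list (13 of 18 genes measured) Tep2 rose by 0.90 and TotX fell by 1.06. In the autophagy list (20 genes) Atg3 rose by 0.74. In the Toll effector list (21 genes) BaraA1 fell by 1.87, and in the Toll pathway list (14 genes) modSP fell by 0.80. Ets21C was the 1 gene that rose in the JNK and wound list (16 genes) and djl in the testis list (26 genes). Of 35 digestive enzyme genes LysX rose by 2.46, LysS fell by 2.28, and LysE, LysD and Ser6 fell too; genes of the Lys family are close copies.

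At 6 h none of the 77 ribosomal protein, 31 proteasome, 9 ovary and egg shell, 19 muscle, 20 neuron and eye, 11 fat body and 9 clock genes changed with cGAMP in the unblocked, blocked or library batch edgeR fits. Adjusted over the list alone in the unblocked fit, the counts at 6 h were 1 higher and 1 lower for haemocytes, and 1 higher and 2 lower for digestive enzymes. They were 1 lower for insulin and lipid use, and 1 higher for the JAK-STAT list and for the JNK list. Over the 9 comparisons camera with the preset correlation gave 61 list calls and with an estimated correlation 18. Preset calls that did not hold with an estimated correlation included the ribosomal proteins at 6 h (median −0.33, adjusted p = 2.9e-05 and 0.89) and purine metabolism at 6 h (median −0.46, adjusted p = 0.021 and 0.79). Muscle at 24 h was another (median −0.57, adjusted p = 0.29 with an estimated correlation). The calls that held were those of the STING, peptide and IMD lists and, in 2 comparisons with c-di-GMP, the ovary list, which did not hold in the blocked fit (adjusted p = 0.31 for c-di-GMP against Tris at 24 h and 0.23 for cGAMP against c-di-GMP at 12 h).

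The libraries fell into 2 sets by composition that cross the treatments. Ribosomal RNA and 7SL RNA took 32.4 to 41.7% of counts in 7 libraries, replicate 3 of every group except Tris and c-di-GMP at 6 h, and 61.3 to 75.9% in the other 20. The first principal component of log expression took 72.7% of the variance, with the 7 libraries at 95.9 to 103.5 and the other 20 between −65.2 and 9.08. At 12 and 24 h the set of 7 coincides with replicate 3 in every group, so that a block on the replicate number compares libraries within a set there. At 6 h the partner in Tris of cGAMP replicate 3 is of the other set.

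**Figure D3:**
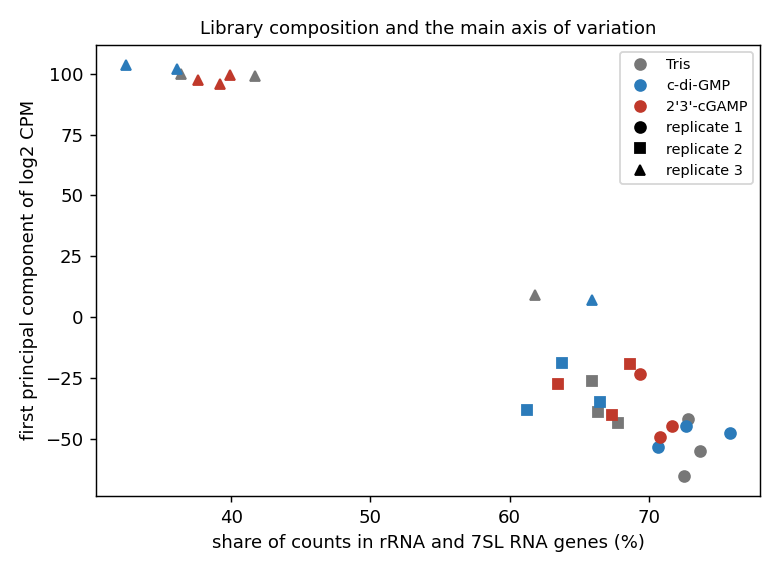
Percent of counts from ribosomal RNA and 7SL RNA (horizontal axis) and the first principal component of log2 CPM (vertical axis) in each of the 27 libraries, by treatment and replicate number. The 7 libraries with 32.4 to 41.7% sit at 95.9 to 103.5 and the other 20 at −65.2 to 9.08.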

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

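The tests here were planned except those of the library batch fit and the arrangements with the block, which were chosen after the result was seen. An F test of the difference between times of the cGAMP response, with the replicate number as a block, called 8 genes, and that difference between groups is why they are listed. The adjusted p was 0.0398 for CG2187 and CG11912 and 0.0497 for alpha-Est2, CG32191, CG10031, CG15293, Cyt-b5-r and mdy. The changes of all 8 were negative at 6 h and nearer to 0 or positive later. CG2187 changed by −1.48, −0.15 and 0.09 at 6, 12 and 24 h (log2, blocked fit, n = 3 per group), and CG11912 by −0.85, 0.50 and 1.46. The carboxylesterase gene alpha-Est2 changed by −1.66, −0.74 and −0.10. CG32191 changed by −1.45, −0.34 and 0.07, CG10031 by −1.32, 0.09 and 0.32 and CG15293 by −0.99, −0.06 and 0.43. The remaining genes were Cyt-b5-r, a cytochrome b5-related gene, with −1.55, −0.26 and 0.08, and mdy, with −1.13, −0.09 and 0.03.

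In the library batch fit the adjusted p of the 8 genes lay between 0.00879 and 0.0244, and without a block it was 0.771 or higher. Times were also drawn within each replicate number, separately for Tris and for cGAMP. In the blocked fit 4 of 50 arrangements, the real one included, gave at least 8 genes, and the highest other gave 206. What gave a count so far above the real one was not tested. Changes with time in either treatment can enter these arrangements as a changed response. The share therefore does not measure chance for these 8 genes, and chance is not excluded for them. In the fit without a block the real count was 0, so that 80 of 80 arrangements gave as many by construction, which says nothing on chance. The highest of these gave 6379 genes and the next 2. The former put 3 libraries of low ribosomal RNA share into 1 group, but another arrangement that did so gave 0, and the source of the 6379 is open. Apart from the library batch term, with which all 8 genes still passed, no other explanation was tested for them.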

How the results depend on the processing

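The library batch, the fit of replicates 1 and 2, the removal of ribosomal and 7SL RNA and the minimum mean count of 100 were tests chosen after the results were seen; the other alternatives were planned. The cause was not tested for any of the changes, except that fewer libraries or genes enter a fit by construction. For c-di-GMP at 6 h Charon went from −0.13 without a block to 1.24 in replicates 1 and 2, and Sting from −0.08 to 0.40 with the block (log2). Both later values come from fits with the block, although replicate 2 did not pair in this comparison.

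With the replicate block cGAMP against Tris gave 480 genes at 6 h (236 higher, 244 lower), 24 at 12 h and 39 at 24 h, in place of 18 (16 higher, 2 lower), 1 and 0. For cGAMP against c-di-GMP it gave 379 (177 higher, 202 lower), 6 and 17 in place of 9, 1 and 0. At 6 h replicate 2 did not pair in this comparison (−0.31), so the count of 379 rests on a pairing that the libraries did not show. The F test of the cGAMP response gave 8 in place of 0 and time in Tris 9 in place of 0. The library batch gave 744, 179 and 262 for cGAMP against Tris, 630, 48 and 106 for cGAMP against c-di-GMP, and 23 and 43 for the F tests. Replicates 1 and 2 alone gave 832, 297 and 538, then 570, 116 and 180, 27 and 27, 8 genes for c-di-GMP against Tris at 6 h, and an overlap of 8 genes between the compounds in place of 0. DESeq2 gave 112, 30 and 42, then 93, 7 and 19, and 2 and 10 for the F tests. With only the groups compared in the fit the counts were 0 at 6 and 12 h for both comparisons of cGAMP.

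With each library left out in turn, cGAMP against Tris ranged from 3 to 62 genes at 6 h, 0 to 7 at 12 h and 0 to 11 at 24 h. For cGAMP against c-di-GMP the ranges were 2 to 9, 0 to 1 and 0 to 1, and c-di-GMP against Tris and both F tests stayed at 0. In the blocked fit the ranges for cGAMP against Tris were 210 to 549 (210 without cGAMP replicate 2, 213 without replicate 1 and 288 without Tris replicate 1) at 6 h. They were 2 to 88 (88 without Tris replicate 3) at 12 h and 0 to 137 at 24 h (137 without cGAMP replicate 3, 0 without cGAMP replicate 1 or Tris replicate 2). In the library batch fit they were 297 to 1070, 23 to 367 and 21 to 979, the last without cGAMP replicate 3 at 24 h. For cGAMP against c-di-GMP the ranges were 131 to 575, 0 to 6 and 0 to 41 in the blocked fit and 347 to 983, 3 to 60 and 0 to 289 in the library batch fit. The blocked range at 6 h rests on a pairing that replicate 2 did not show. Where a group keeps 1 or 2 libraries, these are assumed to vary like the other groups.

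Of the list tests, 61 passed over the 9 comparisons with the preset correlation, 18 with an estimated one and 12 with fry. RLE factors (13 genes for cGAMP against Tris at 6 h), removal of ribosomal and 7SL RNA (12) and a mean count of at least 100 (23) kept every count within 1.5 times. Leaving out the filter on low counts removes and adds no gene, so it says nothing on stability. The counts for c-di-GMP against Tris at 12 and 24 h stayed at 0 under every alternative, except that 1 gene passed at 24 h in the library batch fit with 1 library left out.

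Libraries held 20458214 or more counts outside ribosomal and 7SL RNA, but if both mates of a pair were counted, the number of fragments is lower. In data simulated from the library batch fit the unblocked fit recovered 46% of 4-fold changes for cGAMP against Tris at 6 h. Low counts there do not show that few genes changed.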

Other observations

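The tests of the patterns in the STING list, the egg transcripts and the c-di-GMP libraries were chosen after the results were seen, as were the arrangements with the block; the other splits of the samples were planned. The library batch fit of the F test between times called 23 genes, and 3 of them not called in the blocked fit were Hex-C, Galk and Adgf-D. Hex-C, a hexokinase gene, had cGAMP changes that were 0.93 higher at 12 h and 1.40 higher at 24 h than at 6 h (log2; edgeR adjusted p = 0.0384). For Galk, a galactokinase gene, they were 1.24 and 1.39 higher (edgeR adjusted p = 0.0355). Adgf-D, of the adenosine deaminase family, had cGAMP changes that differed from the one at 6 h by −1.06 at 12 h and −2.08 at 24 h (edgeR adjusted p = 0.0210).

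In the same fit of time in Tris-injected flies, BomS3, a Toll-induced peptide gene, fell by 1.51 from 6 to 24 h (edgeR adjusted p = 0.0255). Peritrophin-15a, which belongs to the chitin-binding proteins of the gut lining, and the cuticle gene Cpr72Ec were higher at 24 h than at 6 h, Cpr72Ec by 1.24 (edgeR adjusted p = 0.0255 and 0.0212).

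The smaller response of the STING list in replicate 3 was weighed first. If the low ribosomal RNA share were its source at 6 h, Tris replicate 3, which has the usual share, would sit with Tris replicates 1 and 2. Its STING list lay 1.90 above them, which argues against that share as the source of the raised Tris level. The test does not bear on the −0.54 of cGAMP replicate 3 at 6 h, since that library has the low share. Other differences of composition stay open. The first principal component of Tris replicate 3 was 9.08 against −41.8 and −26.2 in replicates 1 and 2. Its fat body list differed from theirs by −0.94 and its neuron list by 1.13. At 12 and 24 h no library decides, since 0 replicate 3 libraries of Tris or cGAMP there have the usual ribosomal RNA share, and set and replicate cannot be told apart. RNA of cGAMP-injected flies in Tris replicate 3 at 6 h stays possible. A median share of 35% would be needed for 6 genes of the STING list and 36.9% for 234 other genes that rose, a ratio of 1.05. The 135 genes that fell would need 86.7% there and 71.8% in c-di-GMP replicate 3. The quartiles of the 234 genes were 20.2 and 57.4%, where mixed RNA would give the same share for all genes. These genes were chosen with the libraries that serve as the baseline. A general immune activation would also give a ratio near 1, so the ratio does not tell these sources apart. An immune state of the flies before injection also stays open, as the peptide list was 1.93 higher in Tris replicate 3 and 0.158 higher in c-di-GMP replicate 3 at 6 h, and no biological group of the design separates them.

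Egg shell and yolk transcripts stood out in Tris replicate 1 at 24 h and c-di-GMP replicate 2 at 12 h. Yp1 was at 80.7 and 195 CPM there and at most 0.434 in the other 25 libraries, Yp2 at 140 and 386 against 0.354, and Cp15 at 278 and 429 against 0.417. In all, 6 of the 9 measured ovary genes lay at least 10 times above the other libraries in both. This is consistent with female tissue in the pool, a hypothesis from a marker list fixed beforehand, and no sort or gate is described that would remove it. A sample of females alone under a wrong label is argued against by the testis and accessory gland list, whose median differed from libraries of the same replicate number by 0.110 and −0.187 in these libraries. Each of the comparisons in which the ovary list moved most holds 1 of these libraries. They were c-di-GMP against Tris at 12 h (median 5.70) and at 24 h (median −4.94). Camera with an estimated correlation gave adjusted p = 0.051 and 0.041 for them, and the labels name no sex.

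A shift of the c-di-GMP libraries toward the cGAMP response was weighed last, with shared Tris libraries or the composition of replicate 3 as its possible source. It was measured over genes that rose with cGAMP at the other 2 times, whose Tris libraries differ (208, 526 and 471 genes at 6, 12 and 24 h). In the library batch fit their median c-di-GMP change was 0.162, 0.0709 and 0.0243 with fry p of 0.23, 0.399 and 0.833. In the blocked fit fry p was 0.408, 0.523 and 0.874, so fry called no shift in either fit to all libraries. At 6 h 81.7% of the 208 genes had a positive change in the library batch fit and 71.2% in the blocked fit. The genes were correlated (estimated at 0.39 and 0.38), so these tests neither show nor exclude a small shift at 6 h. In replicates 1 and 2 alone the median was 0.325, 0.121 and 0.0628, with fry p of 0.00043, 0.0373 and 0.354. Camera with an estimated correlation gave p of 0.000949, 0.088 and 0.399 there. At 6 h the value of 0.325, with quartiles of 0.146 and 0.534, argues against both as the whole source of that shift, since it was found without replicate 3 and over genes chosen with other Tris libraries. A weak effect of c-di-GMP at 6 h is a hypothesis from 2 libraries per group, and a difference between these few libraries stays open. That fit uses the block, although replicate 2 did not pair in this comparison. At 12 and 24 h no shift held with an estimated correlation, and the lower values of 0.0243 and 0.0628 leave both explanations open there.

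The 6 libraries of a comparison make 10 splits, too few for a share under 0.05. For cGAMP against Tris the real split gave 18, 1 and 0 genes at 6, 12 and 24 h without a block and the highest other split 0 each time; 1, 1 and 10 of the 10 splits gave as many. With the block the real split gave 480, 24 and 39 and the highest other 1, 0 and 0 (1 of 10 each), and with the library batch 744, 179 and 262 against 178, 0 and 0 (1 of 10 each). For cGAMP against c-di-GMP the real split gave 9, 1 and 0 and the highest other 0 (1, 1 and 10 of 10), and for c-di-GMP against Tris every split gave 0 (10 of 10 at each time). For time in Tris without a block the real arrangement gave 0 genes and the highest other 3. All 80 of 80 arrangements gave as many as 0 by construction, which says nothing on chance. With the block, and times drawn within each replicate number, 1 of 36 arrangements, the real one, gave 9 genes. The highest other gave 3, so the share was under 0.05. That is the smallest share that 36 arrangements can give, and the test was chosen after the result was seen. It argues against chance for these genes but does not exclude it.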
